A study of Homo sapiens with 18 samples.

How the data were processed

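Per the labels' protocols, 16D cells grown in RPMI 1640 were infected with lentivirus for Cas9 and a guide, kept for 6 weeks in DMSO or 10 µM enzalutamide, and lysed for RNA on RNeasy columns. Stranded mRNA libraries were made with a KAPA HyperPrep kit that marks strand with dUTP, and paired ends were read on a NovaSeq X Plus and demultiplexed with Bcl2fastq. STAR and the GRCh38 build are named in the submitters' processing notes without a version; the counting tool and annotation are not given in the sources used here. The deposited table, per the file header and its values, holds TPM for 37347 rows in 18 samples. TPM divides each gene's reads by its length and scales every library to the same sum, so a change in a few abundant transcripts moves the TPM of every other gene, and the depth behind a value is unknown. An mRNA kit and the unknown counting tool also leave the levels of mitochondrial, non-polyadenylated and near-identical genes uncertain.

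Rows without a gene name (10345, with 4.24% to 9.68% of the TPM of a library) were left out, as were 69 rows of 3 symbols with 5 or more rows, and 32 symbols with 2 to 4 rows were summed, which left 26900 symbols. TPM as deposited was changed to log2(TPM + 1), with a pseudocount of 1, and genes at 1 TPM or more in at least 3 libraries were tested (13416 genes). limma 3.58.1 in R 4.3.3 was fitted to all 18 libraries with a mean for each of the 6 groups, which gives 12 residual degrees of freedom, with a trended prior and Benjamini-Hochberg adjustment over genes; genes with an adjusted p under 0.05 were called. Contrasts were each guide against the control guide in vehicle and in enzalutamide, enzalutamide against vehicle within each guide, the interaction of each guide with the drug, and guide 2 less guide 1. A gene was counted for both guides where both passed with the same sign.

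The 30 gene lists (646 distinct genes, 9 of them not analysed here) were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, for lists with at least 3 tested genes, with adjustment over lists within a contrast. An estimated correlation was an alternative. The groups, contrasts, gene lists, tests, alternatives other than those named as chosen later, and the rule for named genes were set before the data were examined. The rule took the 10 rising and 10 falling genes of largest change for enzalutamide in control cells, 8 and 8 for both guides by the smaller of the changes, 4 and 4 for both interactions and 3 and 3 for the difference between guides. Except for interactions, these had at least 5 TPM in the higher group and no overlap of replicates, which chance gives in 10% of genes for 3 libraries against 3. It also took up to 4 members of each list that passed, and OGDHL, PPP1R12C, KLK3, FKBP5, TMPRSS2, CHGA, SYP, ENO2, DLK1, SCGN and OGDH. Some genes that the rule took are not reported here. CDKN1A, NEAT1, the values of BTG2, PLK2 and GDF15 in the libraries labelled guide 2 in vehicle, MYC and FASN there, and genes activated by DUX4 were chosen after their values were seen.

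The alternatives were pseudocounts of 0.1 and 5, no filter or a filter at 5 TPM, median-of-ratios scaling, quantile normalization, removal of the mitochondrially encoded genes (37 rows), a fit of each comparison's own libraries, the replicate number as a block, array weights and leaving out each library in turn. Replicate numbers paired the control and guide 1 libraries in enzalutamide by correlation alone: deviations from group means of same-number libraries correlated at 0.25, 0.11 and 0.20, each best with its own number, and a block was fitted for those libraries. Overlaps between guides were set beside 50 simulations of unchanged groups against the same controls. Coordinates came from GENCODE release 29 on GRCh38, which matched 26712 symbols. The procedure was tested in 5 simulations with 200 changed genes among 13416. For enzalutamide in control cells it recovered 38.5%, 96.4% and 99.7% of genes changed by 0.5, 1 and 2 (log2), with 4.99% false calls. Both guides in vehicle gave 28.7%, 94.0% and 99.7%, with 0.262%, which may not hold as guide 1 vehicle libraries varied most. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.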

Results

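RNA sequencing was carried out on 16D, a castration-resistant prostate cancer cell line, after infection with lentivirus carrying Cas9 and a guide RNA. The control guide targeted the AAVS site, a safe-harbour locus in PPP1R12C, and 2 further guides targeted OGDHL, which encodes a relative of the 2-oxoglutarate dehydrogenase subunit OGDH. Cells with each guide were kept for 6 weeks in DMSO vehicle or in 10 µM enzalutamide, an antiandrogen used to treat prostate cancer. Each of the 6 groups held 3 libraries, 18 in all, with 1 TPM value per gene and library. TPM sums to the same total in each library and keeps no record of sequencing depth, so the depth was unknown. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels are mean TPM ± SD over 3 libraries, and changes are on the log2(TPM + 1) scale, which understates the change of low genes.

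OGDHL (chromosome 10, 49734643 to 49762379, minus strand, GRCh38) was the targeted gene. Its levels were 2.17, 2.17 and 2.11 TPM in the control libraries in vehicle and 3.79, 3.13 and 3.20 TPM in the control libraries in enzalutamide. With guide 1 they were 0.505, 0.689 and 1.35 TPM in vehicle and 1.06, 1.11 and 0.909 TPM in enzalutamide. The libraries labelled guide 2 had 3.08, 3.36 and 2.64 TPM in vehicle and 1.77, 1.63 and 1.80 TPM in enzalutamide. By limma, OGDHL fell with guide 1 in vehicle (log2 change -0.79, adjusted p = 0.0081) and in enzalutamide (-1.11, adjusted p = 7.4e-06), and with guide 2 in enzalutamide (-0.67, adjusted p = 0.0076). In vehicle, OGDHL rose in libraries labelled guide 2 (0.35, adjusted p = 0.020), which does not test DNA cutting. Enzalutamide raised OGDHL in control cells from 2.15 ± 0.0357 to 3.37 ± 0.363 TPM (0.47, adjusted p = 0.0097). The interaction of OGDHL with guide 2, which rests on the vehicle libraries labelled guide 2, passed (-1.03, adjusted p = 1.3e-04), and the interaction with guide 1 was -0.31 (adjusted p = 0.21). By limma the interaction with guide 1 passed with median-of-ratios scaling (-0.49, adjusted p = 7.4e-04), quantile normalization (-0.47, adjusted p = 3.8e-04) and mitochondrially encoded genes removed (-0.57, adjusted p = 0.0058). It also passed with settings chosen after seeing the data: gene-by-gene array weights (-0.13, adjusted p = 0.016), and guide 1 vehicle replicate 3, of the lowest mitochondrial share, as the only library of its group, assumed to vary like the other groups (-0.69, adjusted p = 0.0034, or -0.67, adjusted p = 1.1e-05, with median-of-ratios scaling). The rise in the libraries labelled guide 2 in vehicle did not pass with quantile normalization (0.078, adjusted p = 0.20) or a pseudocount of 0.1 (0.47, adjusted p = 0.074). The rise with enzalutamide in control cells did not pass with that pseudocount (0.62, adjusted p = 0.052). OGDHL with guide 1 in vehicle did not pass in a fit of the 6 libraries of that comparison alone (-0.79, adjusted p = 0.17) or with that single library (-0.42, adjusted p = 0.60), but did with that library and median-of-ratios scaling (-0.40, adjusted p = 0.0097). Leaving out 1 library also ended OGDHL calls: guide 1 in vehicle without control vehicle replicate 1 (-0.79) or guide 1 vehicle replicate 2 (-0.74), guide 2 in vehicle without control vehicle replicate 3 (0.34) or guide 2 vehicle replicate 1 (0.34) or 2 (0.29), and guide 2 in enzalutamide without guide 2 enzalutamide replicate 2 (-0.65).

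PPP1R12C (chromosome 19, 55090913 to 55117559), which holds the control site, had 2.01 ± 0.0430 TPM in control cells in vehicle, 1.33 ± 0.718 TPM with guide 1 and 3.71 ± 0.247 TPM in the libraries labelled guide 2. OGDH had 10.9 ± 0.165, 7.54 ± 2.82 and 13.8 ± 1.36 TPM in the same groups. The neuroendocrine genes CHGA, SYP and SCGN stayed under 1 TPM in every library and were not tested. DLK1 was not analysed here. CHGA had 0.00522 ± 0.00189 TPM and SYP 0.588 ± 0.0953 TPM in control cells in vehicle.

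**Figure D1:**
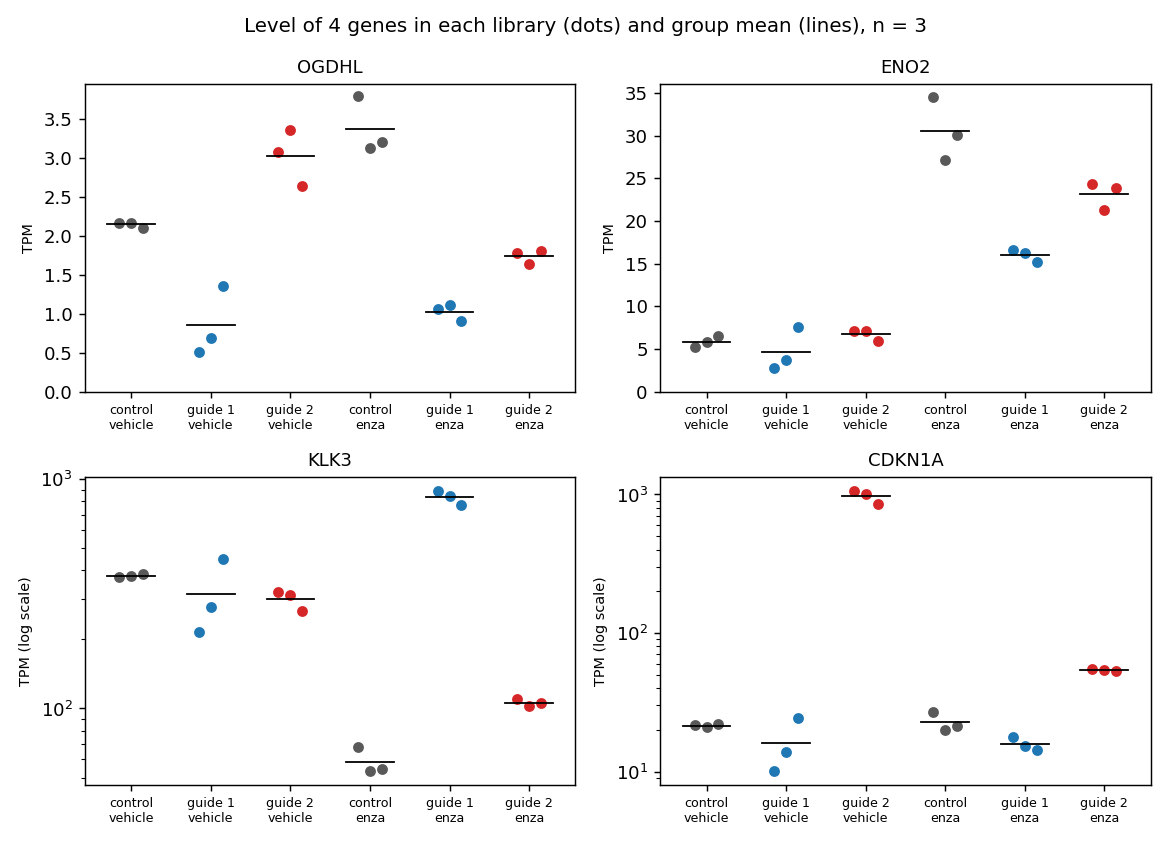
TPM of OGDHL and ENO2 (linear axes) and of KLK3 and CDKN1A (log axes) in each of the 18 libraries, with dots for libraries and lines for group means. OGDHL was lowest with guide 1, KLK3 was highest with guide 1 in enzalutamide, and CDKN1A was highest in the libraries labelled guide 2 in vehicle.

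Mitochondrially encoded genes, which encode respiratory chain subunits and RNAs of the mitochondrial ribosome, held most of the TPM of every library. Their share was 54.5 ± 0.904% in control cells in vehicle and 67.0 ± 8.65% with guide 1 in vehicle, where the 3 libraries had 73.8%, 69.9% and 57.2%. The other groups had 54.6 ± 4.79% (labelled guide 2, vehicle), 55.8 ± 5.01% (control, enzalutamide), 58.9 ± 1.38% (guide 1, enzalutamide) and 59.4 ± 2.63% (guide 2, enzalutamide). The libraries labelled guide 2 in vehicle stood apart in other ways. Their Pearson correlation with the other libraries across genes was 0.884 to 0.922, against 0.950 to 0.998 between all other pairs. Genes are not independent replicates. These 3 libraries listed 1525 ± 112 rows at 0, against 3973 ± 127 in control cells in vehicle. The nuclear RNA NEAT1 had 294 ± 10.0 TPM there and 87.2 ± 4.22 TPM in control cells in vehicle (NEAT1 was chosen after its values were seen).

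**Figure D2:**
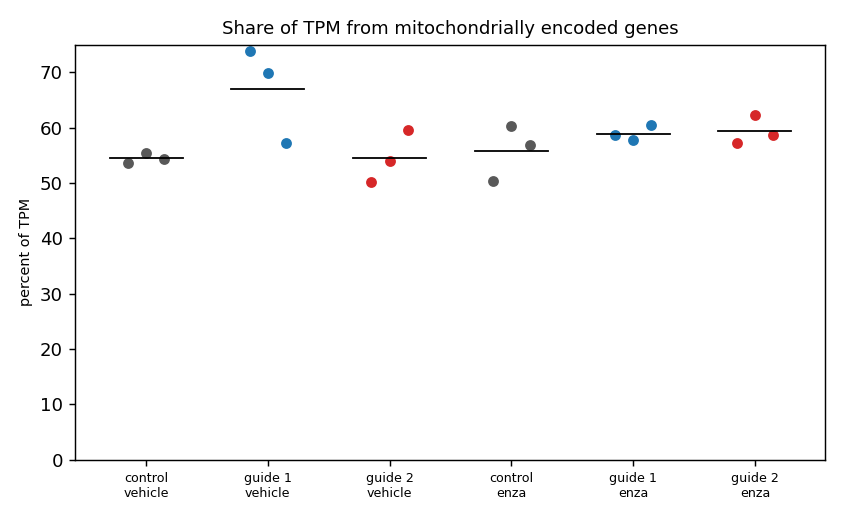
Percent of TPM from mitochondrially encoded genes in each of the 18 libraries, with dots for libraries and lines for group means. The guide 1 libraries in vehicle ranged from 57.2% to 73.8%.

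Enzalutamide was compared with vehicle in control cells to give the drug response without OGDHL targeting. KLK3 (chromosome 19, 50854915 to 50860764), which encodes prostate-specific antigen, fell from 379 ± 5.70 to 58.6 ± 7.92 TPM, and SLC45A3, which encodes prostein, fell from 46.2 ± 1.20 to 2.52 ± 0.568 TPM (n = 3 per group). IGFBP3, a binding protein of insulin-like growth factors, rose from 4.17 ± 0.129 to 215 ± 23.1 TPM, and NTS, which encodes neurotensin, rose from 0.0247 ± 0.00548 to 27.7 ± 3.63 TPM. By limma the log2 changes were -2.68 (adjusted p = 4.4e-09) for KLK3, -3.76 (adjusted p = 2.9e-10) for SLC45A3, 5.38 (adjusted p = 6.9e-15) for IGFBP3 and 4.80 (adjusted p = 5.3e-16) for NTS. TMPRSS2, a protease gene under androgen control, had 9.79 ± 0.280 and 4.42 ± 0.737 TPM (limma adjusted p = 7.5e-05, lower in 3 of 3 libraries). Of 13416 genes, 2796 changed, 1245 higher and 1551 lower, of which 191 and 243 by at least 2-fold. The count was 4990 without guide 1 vehicle replicate 3, and 6944 with median-of-ratios scaling.

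Among the other falling genes with the largest changes, DUSP4, a phosphatase of MAP kinases, changed by -4.46, S100P by -3.70, the transcriptional regulator HES6 by -3.53, RGS2, a regulator of G-protein signalling, by -3.41, the sialyltransferase gene ST6GALNAC1 by -3.09 and the protease gene ADAMTS1 by -3.02 (all limma adjusted p at or under 9.1e-08, lower in 3 of 3 libraries). 3 of the UGT2B glucuronosyltransferase genes were lower too: UGT2B11 by -6.05, UGT2B28 by -5.16 and UGT2B10 by -3.58, values that are uncertain because these genes are near-identical. Rising genes were LRRN1 (5.21), ADRA2A, an adrenergic receptor (5.16), the pseudokinase gene TRIB2 (4.20), LRATD1 (3.53), GASK1B (3.04) and CAMK2N1, an inhibitor of calmodulin-dependent kinase (3.01). AIDA rose from 8.62 ± 0.291 to 183 ± 26.8 TPM and its copy AIDAP1 from 9.16 ± 1.06 to 177 ± 25.3 TPM, and the split of reads between them is uncertain. ENO2, a neuronal enolase, rose by 2.21.

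Androgen-responsive genes moved together in control cells (counts in parentheses are adjusted over the list alone): 0 of 23 rose and 21 fell (0 and 21; camera adjusted p = 1.7e-23, adjusted p = 0.69 with an estimated correlation). Their examples were KLK3, SLC45A3, ACSL3 (-2.62) and MAF (-2.72). Of the androgen-repressed genes, 4 of 7 rose and 2 fell (5 and 2; camera adjusted p = 0.0060, adjusted p = 0.90 with an estimated correlation). OPRK1, an opioid receptor (2.15), and CAMK2N1 rose in it, and UGT2B15 (-2.77) and UGT2B17 (-2.24), enzymes that inactivate androgens, fell, against the list's name, though their near-identical sequences leave these values uncertain. For steroid hormone metabolism, 0 of 9 rose and 7 fell (0 and 8; camera adjusted p = 1.9e-08, adjusted p = 0.73 with an estimated correlation), led by UGT2B genes. Among glucocorticoid receptor targets 0 of 9 rose and 5 fell (0 and 6; camera adjusted p = 0.0022, adjusted p = 0.90 with an estimated correlation), with ZBTB16 (-1.14), CEBPD (-1.68) and FKBP5 (-1.50). Fatty acid synthesis genes followed, as 0 of 15 rose and 11 fell (0 and 11; camera adjusted p = 7.7e-09, adjusted p = 0.90 with an estimated correlation), with ELOVL7 (-2.73), ELOVL5 (-2.27), SCD (-1.80) and FASN (-1.82). For cholesterol synthesis 1 of 23 rose and 18 fell (1 and 20; camera adjusted p = 9.4e-09, adjusted p = 0.90 with an estimated correlation), with STARD4 (-2.01) and FDFT1 (-1.98).

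Several metabolic and stress groups were lower (counts adjusted over the list alone in parentheses). In the hypoxia response list 3 of 17 rose and 12 fell (3 and 13; camera adjusted p = 1.6e-04, adjusted p = 0.90 with an estimated correlation), with NDRG1 (-2.11), LOX (-1.45) and BHLHE40 (-1.09). For glycolysis 1 of 20 rose and 7 fell (1 and 8; camera adjusted p = 0.011, adjusted p = 0.90 with an estimated correlation), with HK2 (-1.31) and LDHA (-1.13). The nuclear-encoded respiratory chain had few calls, as 0 of 72 rose and 8 fell (0 and 4; camera adjusted p = 0.0045, adjusted p = 0.90 with an estimated correlation), with CYCS (-0.60). In the list of ATF4 targets 0 of 24 rose and 10 fell (0 and 16; camera adjusted p = 1.6e-04, adjusted p = 0.90 with an estimated correlation), with TRIB3 (-0.87) and GDF15 (-1.63). Of unfolded protein response genes 0 of 18 rose and 6 fell (0 and 8; camera adjusted p = 0.021, adjusted p = 0.90 with an estimated correlation), with SDF2L1 (-0.68). Cell cycle genes included AURKB (-0.63) and PLK1 (-0.67), and 0 of 36 rose and 10 fell (0 and 10; camera adjusted p = 2.9e-04, adjusted p = 0.90 with an estimated correlation). Mesenchymal genes included SNAI2 (-2.06) and VIM (-1.62), and 2 of 10 rose and 5 fell (2 and 6; camera adjusted p = 0.011, adjusted p = 0.90 with an estimated correlation).

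Higher groups (counts adjusted over the list alone in parentheses) were p53 targets, where 5 of 23 rose and 1 fell (6 and 1; camera adjusted p = 0.011, adjusted p = 0.90 with an estimated correlation), with SESN1 (1.79), PLK2 (2.64) and BTG2 (1.62). They also included type I interferon genes, where 4 of 13 rose and 1 fell (6 and 1; camera adjusted p = 0.017, adjusted p = 0.90 with an estimated correlation), with DTX3L (0.74) and IFIT1 (0.58).

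The remaining lists did not pass limma's camera test for enzalutamide in control cells. Parentheses hold the counts adjusted over the list alone. For neuroendocrine markers 2 rose and 2 fell of 5 (3 and 2, adjusted p = 0.27). For prostate luminal markers 4 rose and 7 fell of 17 (4 and 8, adjusted p = 0.46). For prostate basal markers 1 rose and 1 fell of 5 (1 and 1, adjusted p = 0.54). For stemness genes 3 rose and 3 fell of 12 (3 and 3, adjusted p = 0.71). SOX9, a transcription factor of stem and progenitor cells, rose (2.89) and SOX4 fell (-1.47). For antigen presentation genes 3 rose and 1 fell of 11 (3 and 1, adjusted p = 0.16). For NF-kB response genes 1 rose and 2 fell of 7 (1 and 2, adjusted p = 0.92). For the TCA cycle 0 rose and 2 fell of 26 (0 and 1, adjusted p = 0.28). For mitochondrially encoded genes 1 rose and 0 fell of 13 (1 and 0, adjusted p = 0.42). For pyrimidine and deoxynucleotide synthesis 0 rose and 4 fell of 21 (0 and 4, adjusted p = 0.28). For purine synthesis 1 rose and 2 fell of 16 (1 and 2, adjusted p = 0.42). For 2-oxoglutarate-dependent dioxygenases 2 rose and 4 fell of 29 (2 and 6, adjusted p = 0.42). For ribosome biogenesis genes 0 rose and 2 fell of 24 (0 and 0, adjusted p = 0.20). For leukocyte markers 1 rose and 1 fell of 4 (1 and 2, adjusted p = 0.29). 

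The direction of the test, which is against other genes, the list median and the list mean differed in sign for neuroendocrine markers and NF-kB response genes. In the mean of the guides in vehicle they differed for androgen-repressed genes, glucocorticoid receptor and its targets, steroid hormone metabolism, mesenchymal genes and 2-oxoglutarate-dependent dioxygenases. In the mean of the guides in enzalutamide they did for steroid hormone metabolism, neuroendocrine markers, mesenchymal genes, type I interferon response genes, NF-kB response genes, the nuclear-encoded respiratory chain, pyrimidine and deoxynucleotide synthesis, purine synthesis, glycolysis, hypoxia response genes, ATF4 targets, p53 targets, cholesterol synthesis and fatty acid synthesis, and in the mean of the interactions for steroid hormone metabolism, NF-kB response genes and hypoxia response genes. None of these passed in that test. For single guides, lists that passed and differed were prostate basal markers (guide 1, vehicle), prostate luminal markers (guide 1, enzalutamide), neuroendocrine markers (guide 2, enzalutamide), p53 targets (interaction with guide 1), the nuclear-encoded respiratory chain and ATF4 targets (interaction with guide 2), and some that did not pass differed too. For enzalutamide in control cells no list passed with an estimated correlation, where 1 had an unadjusted p under 0.05. With median-of-ratios scaling and an estimated correlation, chosen after seeing the data, these passed: androgen-responsive genes (adjusted p = 0.0027), glucocorticoid receptor and its targets (adjusted p = 0.046), steroid hormone metabolism (adjusted p = 0.046), type I interferon response genes (adjusted p = 0.046), p53 targets (adjusted p = 0.048), cell cycle genes (adjusted p = 0.022), cholesterol synthesis (adjusted p = 0.021) and fatty acid synthesis (adjusted p = 0.0099). Of the fibroblast and endothelial markers, 1 and 0 were tested, COL1A1 at 6.51 ± 0.0959 TPM in control cells in vehicle and 3.47 ± 0.138 TPM in enzalutamide.

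Guide 1 was compared with the control guide in vehicle. The mitochondrially encoded genes were the group that rose: 11 of 13 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 2.9e-61, adjusted p = 0.0062 with an estimated correlation), with MT-ND3, a complex I subunit, going from 11798 ± 253 to 15121 ± 3053 TPM (n = 3). Genes of the nuclear-encoded respiratory chain fell, with a median -0.27 relative to that of all genes, as 0 of 72 rose and 68 fell (0 and 70 adjusted over the list alone; camera adjusted p = 1.3e-05, adjusted p = 0.90 with an estimated correlation), with ATP5F1D from 83.5 ± 3.97 to 44.8 ± 22.1 TPM and CYC1 from 216 ± 6.87 to 121 ± 64.3 TPM. Cell cycle genes lay below other genes too: 0 of 36 rose and 30 fell (0 and 31 over the list alone, camera adjusted p = 0.0092, adjusted p = 0.90 with an estimated correlation). Prostate basal markers (median -0.0093, limma camera adjusted p = 4.7e-04, adjusted p = 0.45 with an estimated correlation) lay above the rest. At 6.02 TPM or less the log2 scale understates their change, so level may set their place. By limma 7757 genes changed, 41 higher and 7716 lower, with a median change of all genes of -0.32, beside the higher mitochondrial share of these libraries. The split was 3197 higher and 2802 lower with median-of-ratios scaling, 3028 and 2554 with quantile normalization and 3146 and 1852 with mitochondrial genes removed, with median changes of all genes of 0.011, 0.016 and 0.019, and 157 calls had the opposite sign with median-of-ratios scaling. The count was 8, 3825 and 13 without control vehicle replicate 1, 2 or 3, and 14 and 10 without guide 1 vehicle replicate 1 or 2. With guide 1 replicate 3 alone (chosen after seeing the data) the median of all genes was -0.024. In a fit of the comparison's own 6 libraries limma called 0 genes, with 3588 at an unadjusted p under 0.05.

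The libraries labelled guide 2 in vehicle differed from control cells in many genes. CDKN1A, which encodes the cell cycle inhibitor p21, rose from 21.4 ± 0.559 to 973 ± 112 TPM, and GDF15, a stress-induced cytokine, rose from 13.6 ± 1.70 to 413 ± 51.6 TPM (limma log2 changes 5.43 and 4.82, adjusted p = 1.2e-13 and 1.0e-12). PLK1, a mitotic kinase, fell from 31.9 ± 0.346 to 2.29 ± 0.265 TPM and CDC20, an activator of the anaphase-promoting complex, fell from 75.8 ± 1.66 to 5.71 ± 0.708 TPM. MYC fell from 167 ± 3.94 to 51.3 ± 5.82 TPM and FASN from 678 ± 9.17 to 121 ± 14.2 TPM. CDKN1A and the values of GDF15 here were chosen after they were seen, and OGDHL was not lower in these libraries. Among p53 targets 23 of 23 rose and 0 fell (23 and 0 adjusted over the list alone; camera adjusted p = 2.7e-14, adjusted p = 0.74 with an estimated correlation), with BTG2 from 42.0 ± 0.659 to 402 ± 37.2 TPM. For cell cycle genes 2 of 36 rose and 34 fell (2 and 34 adjusted over the list alone; camera adjusted p = 1.8e-23, adjusted p = 0.74 with an estimated correlation). For ribosome biogenesis genes 0 of 24 rose and 22 fell (0 and 22 adjusted over the list alone; camera adjusted p = 3.1e-10, adjusted p = 0.93 with an estimated correlation). By limma 7920 genes changed, 5500 higher and 2420 lower, 1558 and 479 by at least 2-fold, with a median change of all genes of 0.18. The split was 5605 higher and 4745 lower with median-of-ratios scaling and 4768 and 5633 with quantile normalization, with median changes of 0.038 and -0.057.

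Genes that changed with both guides in vehicle were mostly lower. SNRPB, a core protein of the spliceosome, had 66.8 ± 1.35 TPM in control cells, 34.4 ± 20.7 TPM with guide 1 and 30.5 ± 4.29 TPM in the libraries labelled guide 2. LY6E had 67.2 ± 2.83, 35.7 ± 23.9 and 31.2 ± 3.39 TPM, and SLC25A10, the mitochondrial dicarboxylate carrier, had 25.3 ± 0.866, 12.8 ± 9.99 and 10.3 ± 1.29 TPM. MALAT1, a nuclear RNA, was higher, at 1031 ± 74.3 and 1531 ± 111 TPM against 711 ± 41.3 TPM. The log2 changes with guide 1 and guide 2 were -1.09 and -1.11 for SNRPB, -1.10 and -1.09 for LY6E, -1.18 and -1.23 for SLC25A10, -1.11 and -1.08 for ISOC2, -1.06 and -1.52 for BHLHA15 and -1.33 and -1.38 for the mitochondrial transfer RNA gene MT-TL2. They were 0.54 and 1.10 for MALAT1, 0.38 and 3.02 for KRTAP5-1, 0.57 and 1.45 for FOXH1 and 0.45 and 0.93 for EIF5-DT (limma adjusted p under 0.05 with both guides). The pseudogenes ATP5MC1P2 (-1.46 and -1.43) and NPM1P12 (-1.26 and -1.13) are uncertain because they share reads with their parent genes. By limma 1640 genes passed with the same sign, 12 higher and 1628 lower, and 2480 passed with opposite signs. Independent lists would share 16.8 and 1392, and part of any excess may come from the shared controls. The changes with the guides correlated across genes at 0.207 against 0.499 in 50 simulations of unchanged groups, with a covariance of 0.0426 against 0.0160. The split was 1362 higher and 1227 lower with median-of-ratios scaling, 1057 and 1182 with quantile normalization and 1694 and 617 with mitochondrial genes removed. The count was 3, 778 and 6 without control vehicle replicate 1, 2 or 3. It was 8, 6 and 2838 without guide 1 vehicle replicate 1, 2 or 3. Fits of each comparison's own libraries gave 0 (limma), where 1241 genes had an unadjusted p under 0.05.

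Gene lists were tested with limma's camera on the mean of the guides in vehicle, and members were counted where both guides passed with the same sign (in parentheses, adjusted over the list alone). Lists lower than other genes included cell cycle genes, with AURKB (-0.75 and -2.24) and E2F1 (-0.80 and -1.36), and purine synthesis, with PFAS (-0.73 and -1.53) and IMPDH1 (-0.80 and -0.79). In the TCA cycle 0 rose and 6 fell of 26 (0 and 6, adjusted p = 0.0070). In the nuclear-encoded respiratory chain 0 rose and 11 fell of 72 (0 and 7, adjusted p = 5.6e-04), and both had adjusted p = 0.92 with an estimated correlation. In pyrimidine and deoxynucleotide synthesis 0 rose and 9 fell of 21 (0 and 9, adjusted p = 0.0023). In purine synthesis 0 rose and 12 fell of 16 (0 and 13, adjusted p = 1.5e-04), and both had adjusted p = 0.92 with an estimated correlation. In glycolysis 0 rose and 6 fell of 20 (0 and 8, adjusted p = 0.0011). In ATF4 targets 0 rose and 12 fell of 24 (0 and 12, adjusted p = 0.021), and both had adjusted p = 0.92 with an estimated correlation. In cell cycle genes 0 rose and 28 fell of 36 (0 and 29, adjusted p = 8.0e-19, or adjusted p = 0.76 with an estimated correlation). In ribosome biogenesis genes 0 rose and 19 fell of 24 (0 and 20, adjusted p = 6.8e-08, or adjusted p = 0.92 with an estimated correlation).

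In cholesterol synthesis 0 rose and 12 fell of 23 (0 and 14, adjusted p = 4.7e-05). In fatty acid synthesis 0 rose and 8 fell of 15 (0 and 9, adjusted p = 0.0026), and both had adjusted p = 0.92 with an estimated correlation. In unfolded protein response 0 rose and 7 fell of 18 (0 and 7, adjusted p = 0.0032, or adjusted p = 0.92 with an estimated correlation). Fatty acid synthesis included FASN (-0.91 and -2.49) and SREBF1 (-0.81 and -1.66), and ribosome biogenesis FBL (-0.72 and -1.58) and NOP2 (-0.59 and -0.77). Prostate basal markers, p53 targets and leukocyte markers lay above other genes. In prostate basal markers 0 rose and 0 fell of 5 (0 and 0, adjusted p = 1.5e-04). In p53 targets 0 rose and 0 fell of 23 (0 and 0, adjusted p = 3.8e-20), and both had adjusted p = 0.50 with an estimated correlation. In leukocyte markers 0 rose and 0 fell of 4 (0 and 0, adjusted p = 0.047, or adjusted p = 0.90 with an estimated correlation). Of the p53 targets, 23 rose in the libraries labelled guide 2 and 10 fell with guide 1. The basal and leukocyte markers stood at low levels, and the leukocyte markers CD68 and LYZ had 10.6 and 1.16 TPM in the libraries labelled guide 2 in vehicle. These 14 lists move with the libraries that stand apart and with the higher mitochondrial share of guide 1. The genes FKBP5, C1orf116, EZH2, EPCAM and SDHB fell with guide 1 in vehicle in TPM and had the opposite sign with median-of-ratios scaling. With that scaling and an estimated correlation these passed: pyrimidine and deoxynucleotide synthesis (adjusted p = 0.020), purine synthesis (adjusted p = 0.0017), p53 targets (adjusted p = 9.7e-05), cell cycle genes (adjusted p = 5.9e-04), ribosome biogenesis genes (adjusted p = 0.0051), cholesterol synthesis (adjusted p = 0.039) and fatty acid synthesis (adjusted p = 0.043).

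In enzalutamide, guide 1 was compared with the control guide. KLK3 was at 834 ± 58.4 TPM with guide 1 against 58.6 ± 7.92 TPM, above its level in control cells in vehicle (379 ± 5.70 TPM, n = 3). ADAMTS1 was at 26.1 ± 0.934 against 2.33 ± 0.498 TPM, SLC45A3 at 22.9 ± 2.08 against 2.52 ± 0.568 TPM and C1orf116, an androgen-regulated gene, at 55.2 ± 3.65 against 16.7 ± 2.90 TPM. Lower genes included IGFBP3, at 38.6 ± 3.00 against 215 ± 23.1 TPM, and SYT4, a synaptotagmin, at 3.50 ± 0.276 against 22.7 ± 3.83 TPM. By limma the log2 changes were 3.82 (adjusted p = 2.1e-10) for KLK3, 3.04 (adjusted p = 8.8e-11) for ADAMTS1, 2.77 (adjusted p = 8.7e-08) for SLC45A3 and -2.44 (adjusted p = 1.7e-09) for IGFBP3. By limma 948 genes changed, 289 higher and 659 lower. The split was 2364 higher and 2401 lower with median-of-ratios scaling, 2387 and 2271 with quantile normalization and 2350 and 1911 with mitochondrial genes removed. The count was 2366 without guide 1 vehicle replicate 3, and 608 and 557 without guide 1 enzalutamide replicate 2 or 3.

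Androgen-responsive genes with guide 1 in enzalutamide were mostly higher: 16 of 23 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 4.3e-23, adjusted p = 0.72 with an estimated correlation). In the list of androgen-repressed genes, 1 of 7 rose and 5 fell (1 and 5 adjusted over the list alone; camera adjusted p = 3.9e-04, adjusted p = 0.96 with an estimated correlation), with OPRK1 (-1.61) and CAMK2N1 (-1.11) lower. Among cell cycle genes 4 of 36 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 1.4e-08, adjusted p = 0.96 with an estimated correlation). Among p53 targets 0 of 23 rose and 5 fell (0 and 7 adjusted over the list alone; camera adjusted p = 0.013, adjusted p = 0.96 with an estimated correlation), and among antigen presentation genes 0 of 11 rose and 3 fell (0 and 5 adjusted over the list alone; camera adjusted p = 0.023, adjusted p = 0.96 with an estimated correlation). Prostate luminal markers had a median of -0.090 and a mean of 0.30, which differ in sign, and 5 of 17 rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.028, adjusted p = 0.96 with an estimated correlation). With median-of-ratios scaling and an estimated correlation these passed for guide 1 in enzalutamide: androgen-responsive genes (adjusted p = 0.0037) and cell cycle genes (adjusted p = 0.0037).

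Guide 2 in enzalutamide moved fewer genes. KLK3 was at 106 ± 3.52 against 58.6 ± 7.92 TPM, CDKN1A at 54.1 ± 0.928 against 22.7 ± 3.70 TPM and LRATD1 at 4.15 ± 0.341 against 17.2 ± 2.76 TPM (limma log2 changes 0.85, 1.23 and -1.81, adjusted p = 0.030, 0.0037 and 4.6e-08). By limma 168 genes changed, 91 higher and 77 lower. In the p53 list 2 of 23 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 6.6e-13, adjusted p = 0.66 with an estimated correlation). In the cell cycle list 0 of 36 rose and 1 fell (0 and 21 adjusted over the list alone; camera adjusted p = 6.8e-16, adjusted p = 0.66 with an estimated correlation), and in the androgen-responsive list 2 of 23 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.031, adjusted p = 0.87 with an estimated correlation). The count was 274 and 678 without guide 1 vehicle replicate 1 or 3, 68 without control enzalutamide replicate 3, and 77, 78 and 80 without guide 2 enzalutamide replicate 1, 2 or 3, and 2383 with median-of-ratios scaling.

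Genes that changed with both guides in enzalutamide included ADCYAP1, which encodes the neuropeptide PACAP, at 6.07 ± 0.844 TPM in control cells, 0.814 ± 0.0239 TPM with guide 1 and 0.307 ± 0.0813 TPM with guide 2. LRATD1 had 17.2 ± 2.76, 5.11 ± 0.389 and 4.15 ± 0.341 TPM, and IGFBP5, a binding protein of insulin-like growth factors, 5.83 ± 1.09, 1.72 ± 0.121 and 1.51 ± 0.197 TPM. C1orf116 was higher, with 16.7 ± 2.90, 55.2 ± 3.65 and 27.5 ± 1.94 TPM. The log2 changes with guide 1 and guide 2 were -1.95 and -2.43 for ADCYAP1, -1.57 and -1.81 for LRATD1, -1.71 and -1.30 for KLHDC9, -1.32 and -1.43 for IGFBP5, -1.82 and -1.04 for TRIB2, -2.39 and -0.94 for SYT4, -1.61 and -0.91 for OPRK1 and -0.91 and -0.94 for the transcription factor FOXQ1. Rising genes were KLK3 (3.82 and 0.85), C1orf116 (1.67 and 0.70), SFTPA2 (1.08 and 0.83), ARG2, a mitochondrial arginase (0.93 and 0.64), BCHE (0.51 and 0.97) and DEFB132 (0.45 and 0.78), all with limma adjusted p under 0.05. By limma 62 genes passed with the same sign, 17 higher and 45 lower, and 24 with opposite signs. Independent lists would share 1.96 and 3.78. The highest of 50 simulations of unchanged groups gave 2, but regrouped real libraries gave up to 675. Part of the excess may come from the shared controls. Across genes the changes correlated at 0.0691 against 0.499 simulated, with a covariance of 0.00298 against 0.00521. The split was 357 higher and 253 lower with median-of-ratios scaling, 315 and 273 with quantile normalization and 334 and 167 with mitochondrial genes removed. The count was 163 without guide 1 vehicle replicate 3, 37 and 25 without control enzalutamide replicate 1 or 3, and 35, 33 and 35 without guide 2 enzalutamide replicate 1, 2 or 3.

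By limma's camera on the mean of the guides in enzalutamide, 4 lists were higher than other genes (counts in parentheses are adjusted over the list alone). In androgen-responsive genes 2 rose and 0 fell of 23 (2 and 0, adjusted p = 1.6e-24, or adjusted p = 0.62 with an estimated correlation). In glucocorticoid receptor and its targets 0 rose and 0 fell of 9 (0 and 0, adjusted p = 9.2e-04). In prostate luminal markers 1 rose and 0 fell of 17 (3 and 0, adjusted p = 2.4e-05), and both had adjusted p = 0.98 with an estimated correlation. In mitochondrially encoded genes 0 rose and 0 fell of 13 (0 and 0, adjusted p = 3.5e-04, or adjusted p = 0.98 with an estimated correlation). Members of the androgen-responsive list that rose with both guides were KLK3 and C1orf116. The other 24 lists did not pass. With median-of-ratios scaling and an estimated correlation these passed: androgen-responsive genes (adjusted p = 0.0020) and glucocorticoid receptor and its targets (adjusted p = 0.013). 

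Between the guides in enzalutamide, LINC00161 had 21.3 ± 1.46 TPM with guide 1 and 0.400 ± 0.126 TPM with guide 2, MAGEA1, a cancer-testis antigen, 27.4 ± 1.08 and 2.34 ± 0.165 TPM, and PHLDA1 12.2 ± 0.689 and 0.516 ± 0.0358 TPM. Higher with guide 2 were NTS (7.65 ± 0.546 and 53.5 ± 4.50 TPM), IGFBP3 (38.6 ± 3.00 and 202 ± 13.4 TPM) and SLPI (4.68 ± 0.254 and 24.2 ± 0.213 TPM). KLK3 differed between the guides by -2.96 (limma adjusted p = 6.8e-09). By limma 1737 genes differed, 845 higher and 892 lower with guide 2. The count was 3671 without guide 1 vehicle replicate 3, 1095, 1155 and 1020 without guide 1 enzalutamide replicate 1, 2 or 3, and 1112, 1099 and 1086 without guide 2 enzalutamide replicate 1, 2 or 3. In vehicle 10052 genes differed, 8895 higher and 1157 lower in the libraries labelled guide 2 (median of all genes 0.54), or 5670 higher and 4973 lower with median-of-ratios scaling, 4899 and 5857 with quantile normalization and 6828 and 3663 with mitochondrial genes removed. SSU72P4 and SSU72P5 (8.04 and 6.55) and H3Y1 (6.81) were higher and PLK1 (-2.74), CDC20 (-2.61) and CDC20P1 (-2.80) lower, where the SSU72P, H3Y1 and CDC20P1 values are uncertain because of near-identical copies.

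Enzalutamide was also compared with vehicle within each guide. With guide 1, IGFBP3 rose from 3.27 ± 0.859 to 38.6 ± 3.00 TPM, NTS from 0.0260 ± 0.00306 to 7.65 ± 0.546 TPM and KLK3 from 314 ± 122 to 834 ± 58.4 TPM, while DUSP4 fell from 36.6 ± 12.1 to 1.54 ± 0.119 TPM. By limma the change of KLK3 was 1.47 (adjusted p = 2.3e-05). With guide 1 4007 genes changed, 3532 higher and 475 lower (median of all genes 0.23), or 3272 higher and 3231 lower with median-of-ratios scaling, 3257 and 3177 with quantile normalization and 2756 and 3224 with mitochondrial genes removed. That count was 1752, 1491 and 9927 without guide 1 vehicle replicate 1, 2 or 3, and 1716, 2058 and 2496 without guide 1 enzalutamide replicate 1, 2 or 3. For guide 2 the comparison rests on the vehicle libraries labelled guide 2, which stand apart and whose OGDHL was not lower than in control cells. KLK3 had 299 ± 29.5 TPM in those libraries and 106 ± 3.52 TPM with guide 2 in enzalutamide, CDKN1A 973 ± 112 and 54.1 ± 0.928 TPM and NTS 0.0314 ± 0.00983 and 53.5 ± 4.50 TPM. By limma 7983 genes differed, 1507 higher and 6476 lower in enzalutamide (median -0.30), or 4690 higher and 5219 lower with median-of-ratios scaling, 5577 and 4545 with quantile normalization and 3200 and 6777 with mitochondrial genes removed.

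The interaction tests asked whether the drug response differed between each guide and the control guide. SLC45A3 fell with enzalutamide from 46.2 ± 1.20 to 2.52 ± 0.568 TPM in control cells, and had 30.1 ± 14.3 and 22.9 ± 2.08 TPM with guide 1. LRRN1 rose from 1.08 ± 0.0283 to 76.6 ± 12.4 TPM in control cells and from 1.09 ± 0.139 to 21.5 ± 0.856 TPM with guide 1. SOX9 rose from 7.25 ± 0.387 to 60.8 ± 10.8 TPM in control cells, and had 5.06 ± 0.620 and 25.9 ± 1.68 TPM with guide 1. The interactions with guide 1 and guide 2 were 4.15 and 1.20 for KLK3, -0.74 and -1.08 for SOX9, 2.15 and 1.20 for C1orf116 and 1.34 and 1.00 for CEBPD (limma adjusted p under 0.05 with both). Values and counts with guide 2 or both guides rest on the vehicle libraries labelled guide 2, which stand apart and whose OGDHL was not lower. In enzalutamide SOX9 (-0.16, adjusted p = 0.76) and CEBPD (-0.011, adjusted p = 0.99) did not pass with guide 2 against the control guide. By limma 932 genes differed in response with guide 1, 761 positive and 171 negative (median of all genes 0.27), or 2156 higher and 2363 lower with median-of-ratios scaling, 2044 and 2197 with quantile normalization and 1755 and 2059 with mitochondrial genes removed. That count was 432, 466 and 468 without control vehicle replicate 1, 2 or 3, 582, 404 and 8771 without guide 1 vehicle replicate 1, 2 or 3, 1948, 478 and 433 without control enzalutamide replicate 1, 2 or 3, and 433, 450 and 493 without guide 1 enzalutamide replicate 1, 2 or 3. With guide 2 5849 passed, 1168 positive and 4681 negative (median -0.26), or 4057 higher and 4768 lower with median-of-ratios scaling, 4829 and 4070 with quantile normalization and 2792 and 5939 with mitochondrial genes removed. With both guides 424 passed with the same sign, 315 positive and 109 negative, and 123 with opposite signs. Independent lists would share 66.3 and 59.7, and part of the excess may come from the shared controls. The interactions correlated at 0.363 against 0.502 simulated, with a covariance of 0.0925 against 0.0227. The split was 1331 higher and 1381 lower with median-of-ratios scaling, 1358 and 1115 with quantile normalization and 917 and 1430 with mitochondrial genes removed. The count was 188, 207 and 207 without control vehicle replicate 1, 2 or 3, 199 and 1725 without guide 1 vehicle replicate 2 or 3, 732, 236 and 187 without control enzalutamide replicate 1, 2 or 3, and 209, 210 and 231 without guide 1 enzalutamide replicate 1, 2 or 3.

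Lists were tested on the mean of the interactions with limma's camera, with counts adjusted over the list alone in parentheses. Androgen-responsive genes had more positive interactions than other genes, that is, a less negative response with the guides than with the control guide, with KLK2 (1.70 and 0.78) beside KLK3 and SLC45A3, and cell cycle genes were positive, with AURKB (1.10 and 1.92) and CCNB1 (0.87 and 1.91). For androgen-responsive genes 10 were positive and 0 were negative of 23 (11 and 1, adjusted p = 5.6e-06). For prostate luminal markers 3 were positive and 0 were negative of 17 (4 and 0, adjusted p = 0.041), and both had adjusted p = 0.79 with an estimated correlation. For the TCA cycle 0 were positive and 0 were negative of 26 (0 and 0, adjusted p = 0.014). For the nuclear-encoded respiratory chain 0 were positive and 0 were negative of 72 (0 and 0, adjusted p = 0.0011), and both had adjusted p = 0.79 with an estimated correlation. For pyrimidine and deoxynucleotide synthesis 1 were positive and 0 were negative of 21 (6 and 0, adjusted p = 0.0019). For purine synthesis 0 were positive and 0 were negative of 16 (2 and 0, adjusted p = 7.6e-05), and both had adjusted p = 0.79 with an estimated correlation. For glycolysis 1 were positive and 0 were negative of 20 (2 and 0, adjusted p = 0.0015). For ATF4 targets 4 were positive and 0 were negative of 24 (10 and 0, adjusted p = 0.0088), and both had adjusted p = 0.79 with an estimated correlation.

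For cell cycle genes 17 were positive and 0 were negative of 36 (26 and 0, adjusted p = 6.7e-21, or adjusted p = 0.62 with an estimated correlation). For ribosome biogenesis genes 3 were positive and 0 were negative of 24 (7 and 0, adjusted p = 1.5e-07). For cholesterol synthesis 3 were positive and 0 were negative of 23 (8 and 0, adjusted p = 1.4e-05), and both had adjusted p = 0.79 with an estimated correlation. For fatty acid synthesis 1 were positive and 0 were negative of 15 (5 and 0, adjusted p = 7.8e-05). For unfolded protein response 2 were positive and 0 were negative of 18 (2 and 0, adjusted p = 0.0088), and both had adjusted p = 0.79 with an estimated correlation. Prostate basal markers, at low levels, and p53 targets lay below other genes. For prostate basal markers 0 were positive and 0 were negative of 5 (0 and 0, adjusted p = 2.1e-04). For p53 targets 0 were positive and 1 were negative of 23 (0 and 1, adjusted p = 2.3e-18), and both had adjusted p = 0.62 with an estimated correlation. SESN1, a p53 target, had interactions of -0.63 and -2.10. These lists draw on the vehicle libraries labelled guide 2, which stand apart, and on the guide 1 vehicle libraries with their higher mitochondrial share. With median-of-ratios scaling and an estimated correlation these passed: androgen-responsive genes (adjusted p = 0.037), pyrimidine and deoxynucleotide synthesis (adjusted p = 0.021), purine synthesis (adjusted p = 0.0013), p53 targets (adjusted p = 8.4e-05), cell cycle genes (adjusted p = 4.4e-04), ribosome biogenesis genes (adjusted p = 0.0062), cholesterol synthesis (adjusted p = 0.029) and fatty acid synthesis (adjusted p = 0.021).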

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

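The tests of background reads, of luminal markers and of scaling for the libraries labelled guide 2 in vehicle, of mitochondrial removal for guide 1 in vehicle, of scaling and of androgen-responsive genes above the vehicle groups for guide 1 in enzalutamide, and of splits that part the pairs were chosen only after the result was seen. Genes with an interaction between guide and enzalutamide by limma were singled out by its size with both guides. With guide 1 and guide 2, positive interactions were SLC45A3 (3.47 and 1.29, adjusted p = 8.6e-07 and 0.0024), TM4SF1 (1.36 and 2.41, adjusted p = 2.2e-05 and 6.2e-10), RNVU1-22 (1.67 and 1.64, adjusted p = 0.014 and 0.0020) and LDHAP2 (1.29 and 1.33, adjusted p = 0.046 and 0.0082). Negative interactions were IGFBP3 (-2.15 and -3.82, adjusted p = 1.8e-06 and 2.8e-11), ADCYAP1 (-1.95 and -2.45, adjusted p = 5.1e-10 and 5.9e-13), LRRN1 (-1.78 and -2.05, adjusted p = 2.0e-06 and 1.7e-08) and TMSB4XP6 (-1.99 and -2.80, adjusted p = 0.0063 and 2.4e-05). Those with guide 2 rest on the vehicle libraries labelled guide 2, whose OGDHL was not lower than in control cells. In enzalutamide guide 2 differed from the control guide by limma for TM4SF1 (0.74, adjusted p = 0.0011), ADCYAP1 (-2.43, adjusted p = 2.2e-13) and LRRN1 (-0.60, adjusted p = 0.015). In that comparison IGFBP3 (-0.086, adjusted p = 0.90), SLC45A3 (0.044, adjusted p = 0.96), RNVU1-22 (-0.24, adjusted p = 0.85), LDHAP2 (-0.11, adjusted p = 0.93) and TMSB4XP6 (-0.53, adjusted p = 0.59) did not pass. RNVU1-22, LDHAP2 and TMSB4XP6 have near-identical copies, so their values are uncertain.

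The libraries labelled guide 2 in vehicle stood apart, with p53 targets higher, cell cycle genes lower and OGDHL higher (call lost with quantile normalization or a pseudocount of 0.1). Uniform background reads were argued against for these lists only. The p53 targets rose by a median of 50.2 TPM (lower quartile 20.3 TPM), olfactory receptor genes by 0.0127 (95th percentile 0.407, median from 0.00946 to 0.0348 TPM). Cell cycle genes had a median log2 ratio of -1.81 relative to genes at 100 TPM or more in control cells. Prostate luminal markers (median 0.10 relative to all genes) argued against cells of another lineage in place of 16D. Median-of-ratios scaling, with 23 p53 targets higher, argued against scaling. A wrong label, which could explain OGDHL, another culture state, such as stress, and an effect of the guide stay open, untested. Guide 2 changes in vehicle and enzalutamide, sharing no library, correlated at 0.48 (guide 1 0.079).

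Most called genes were lower with guide 1 in vehicle, where the mitochondrial share of TPM was higher. A candidate explanation is that a few mitochondrial transcripts took more of the fixed TPM total: with mitochondrially encoded genes removed, 37.1% of the called genes were lower. Why the mitochondrial share differed between these 3 libraries stays open, RNA quality included, and an effect of the guide on it is untested.

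Androgen-responsive genes were higher with guide 1 in enzalutamide than with the control guide. Scaling was argued against, since the 16 genes of the list called higher in TPM were also called under median-of-ratios scaling, where 19 were higher. Cells that escaped the drug, or a mixture with them, cannot be told apart from an effect of the guide. Among 411 other genes that enzalutamide changed by at least 1 on the log2 scale in control cells, the guide 1 libraries kept a median of 62.9% of the change (guide 2 99.3%), between the bounds set for either answer, and 3 androgen-responsive genes, KLK3 among them, lay above both vehicle groups, which a mixture alone would not give for those genes. A biological explanation, that guide 1 weakens the response of these genes to enzalutamide, may hold, but with guide 2 the genes of this list that passed were KLK3 and C1orf116, 2 of 23.

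The libraries of each comparison were also split in other ways and refitted with limma. For comparisons of 3 libraries with 3 there are 10 splits, too few for a share under 0.05. The real split and the highest other split, with the counts at an unadjusted p under 0.05 in parentheses, gave 2796 (4309) genes against 0 (381) for enzalutamide in control cells, 7757 (8819) genes against 8094 (9505) for guide 1 in vehicle and 7920 (8472) genes against 1 (155) for guide 2 in vehicle. They gave 948 (2412) genes against 0 (562) for guide 1 in enzalutamide, 168 (1349) genes against 1 (1139) for guide 2 in enzalutamide and 4007 (6147) genes against 6743 (8152) for enzalutamide with guide 1. The remaining comparisons gave 7983 (8515) genes against 0 (326) for enzalutamide with guide 2, 10052 (10295) genes against 7652 (9016) for guide 2 against guide 1 in vehicle and 1737 (3328) genes against 0 (105) for guide 2 against guide 1 in enzalutamide. The real one included, 1 of 10 splits gave as many, or 2 for guide 1 in vehicle and for enzalutamide with guide 1. For guide 1 in enzalutamide, where replicate numbers pair the libraries, the 3 other splits that part all 3 pairs gave 0 genes (at most 135 at an unadjusted p under 0.05), and those that part 1 pair gave 0 (at most 562). Splits that call more genes than the real one for guide 1 in vehicle and for enzalutamide with guide 1 point to a structure of those libraries, among which the mitochondrial share differs.

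Of larger sets of splits, 3 of 100 splits gave as many for both guides in vehicle (1640 against 7163 in the highest other), 2 of 100 splits gave as many for both guides in enzalutamide (62 against 675) and 3 of 100 splits gave as many for both interactions (424 against 5125). Of splits that part all 3 same-number pairs of control and guide 1 libraries in enzalutamide, as the real split does, 6 of 100 gave as many for both guides in enzalutamide (highest other 722) and 4 of 100 gave as many for both interactions (highest other 6206). Other splits called more genes, so these shares do not exclude chance. For both guides in enzalutamide the 49 splits of the first 100 that part fewer pairs gave at most 1 gene. Chance could not be excluded for single interactions, where 7 of 100 splits gave as many for the interaction with guide 1 (932 against 7998) and 5 of 100 splits gave as many for the interaction with guide 2 (5849 against 6797), and with the pairs parted 6 of 80 gave as many for the interaction with guide 1 (highest other 5249). Except for the interaction with guide 2, the highest splits called several times the real counts, which points to a structure of the samples. As many gene lists were called in 14 of 100 for the mean of the guides in vehicle (14 against 15), 70 of 100 for the mean of the guides in enzalutamide (4 against 18) and 6 of 100 for the mean of the interactions (15 against 19), so chance could not be excluded for these numbers of lists. For enzalutamide in control cells 3 of 10 splits called as many lists (15 against 17), where the splits are too few for a share under 0.05.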

How the results depend on the processing

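The settings that leave out the 2 guide 1 vehicle libraries or the 3 guide 2 vehicle libraries, those that join median-of-ratios scaling to another choice, gene-by-gene array weights and a block within the control and guide 1 enzalutamide libraries were chosen only after the result was seen. The planned array weights did not converge (weights of 8.38e-10 to 1.02e+06) and were not used, and the gene-by-gene weights ran from 0.0288 to 11.04. The number of sequenced fragments is unknown, so the limit that depth sets on low genes could not be given. In 14 of 15 pairs of groups replicate numbers did not pair the libraries, as not every same-number correlation was above 0.1. Of all 45 same-number pairs 10 correlated above 0.1 (from -0.44 to 0.25), and 22 correlated best with their own number against 15 by chance. Results for guide 2 in vehicle, enzalutamide with guide 2 and the interaction with guide 2 rest on the vehicle libraries labelled guide 2, whose OGDHL was not lower. Counts of genes depended on scaling and on the guide 1 vehicle libraries, and list calls on the correlation assumed. Except where a setting changes the number of genes or samples, the cause was not tested.

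With an estimated inter-gene correlation the numbers of lists called were 0 for enzalutamide in control cells, 0 for the mean of the guides in vehicle, 0 for the mean of the guides in enzalutamide and 0 for the mean of the interactions. With a pseudocount of 0.1 the numbers of lists called were 7 for the mean of the guides in enzalutamide, and OGDHL had 0.47 for guide 2 in vehicle (call lost, adjusted p = 0.074) and 0.62 for enzalutamide in control cells (call lost, adjusted p = 0.052). With no filter on low values, which tests more genes, the counts of genes were 5599 for enzalutamide in control cells, 14975 for guide 2 in vehicle, 2360 for guide 1 in enzalutamide, 653 for guide 2 in enzalutamide, 15166 for enzalutamide with guide 2, 1589 for the interaction with guide 1, 11406 for the interaction with guide 2, 17613 for guide 2 against guide 1 in vehicle, 3265 for guide 2 against guide 1 in enzalutamide, 263 for both guides in enzalutamide and 769 for both interactions, and the numbers of lists called were 2 for the mean of the guides in enzalutamide. With a filter at 5 TPM, which tests fewer genes, the counts of genes were 1288 for enzalutamide in control cells, 4256 for guide 2 in vehicle, 371 for guide 1 in enzalutamide, 76 for guide 2 in enzalutamide, 2346 for enzalutamide with guide 1, 4260 for enzalutamide with guide 2, 522 for the interaction with guide 1, 2942 for the interaction with guide 2, 5613 for guide 2 against guide 1 in vehicle, 877 for guide 2 against guide 1 in enzalutamide, 27 for both guides in enzalutamide and 246 for both interactions. With median-of-ratios scaling the counts of genes were 6944 for enzalutamide in control cells, 4765 for guide 1 in enzalutamide, 2383 for guide 2 in enzalutamide, 6503 for enzalutamide with guide 1, 4519 for the interaction with guide 1, 8825 for the interaction with guide 2, 6268 for guide 2 against guide 1 in enzalutamide, 2589 for both guides in vehicle, 610 for both guides in enzalutamide and 2712 for both interactions, and OGDHL had -0.49 for interaction with guide 1 (call gained, adjusted p = 7.4e-04). The sign turned for guide 1 in vehicle for C1orf116 (0.0022), FKBP5 (0.11), HSD17B11 (0.069), SRD5A3 (0.13), EPCAM (0.16), EZH2 (0.094), SDHB (0.0053), ALKBH2 (0.025), PDIA6 (0.041) and MANF (0.031). With quantile normalization the counts of genes were 6874 for enzalutamide in control cells, 4658 for guide 1 in enzalutamide, 2239 for guide 2 in enzalutamide, 6434 for enzalutamide with guide 1, 4241 for the interaction with guide 1, 8899 for the interaction with guide 2, 6117 for guide 2 against guide 1 in enzalutamide, 588 for both guides in enzalutamide and 2473 for both interactions, and OGDHL had 0.078 for guide 2 in vehicle (call lost, adjusted p = 0.20) and -0.47 for interaction with guide 1 (call gained, adjusted p = 3.8e-04). The sign turned for guide 1 in vehicle for C1orf116 (0.021), CENPN (0.022), FKBP5 (0.12), HSD17B11 (0.060), SRD5A3 (0.14), EPCAM (0.18), EZH2 (0.080), CS (0.023), FH (0.028), SDHB (0.0092), ALKBH2 (0.045), PDIA6 (0.085) and MANF (0.074). With mitochondrially encoded genes removed the counts of genes were 6581 for enzalutamide in control cells, 4998 for guide 1 in vehicle, 4261 for guide 1 in enzalutamide, 1892 for guide 2 in enzalutamide, 3814 for the interaction with guide 1, 5760 for guide 2 against guide 1 in enzalutamide, 501 for both guides in enzalutamide and 2347 for both interactions, and OGDHL had -0.57 for interaction with guide 1 (call gained, adjusted p = 0.0058). The sign turned for guide 1 in vehicle for C1orf116 (0.0085), FKBP5 (0.12), HSD17B11 (0.10), SRD5A3 (0.14), EPCAM (0.18), EZH2 (0.12), SDHB (0.012), ALKBH2 (0.032), PDIA6 (0.048) and MANF (0.038). With the replicate number as a block the counts of genes were 586 for the interaction with guide 1 and 281 for both interactions. With fits of each comparison's own libraries, which have fewer samples, the counts of genes were 4457 for enzalutamide in control cells, 0 for guide 1 in vehicle, 1935 for guide 1 in enzalutamide, 412 for guide 2 in enzalutamide, 506 for enzalutamide with guide 1, 346 for the interaction with guide 1, 5557 for guide 2 against guide 1 in enzalutamide, 0 for both guides in vehicle, 122 for both guides in enzalutamide and 174 for both interactions, and OGDHL had -0.79 for guide 1 in vehicle (call lost, adjusted p = 0.17). The block moved no other count of genes or lists by over 1.5 times. A block within the control and guide 1 enzalutamide libraries gave 911 genes for guide 1 in enzalutamide and ended 1 list call there, mitochondrially encoded genes (limma camera adjusted p = 0.049 without and 0.051 with it), and changed no other list or named gene call of that comparison. A pseudocount of 5 moved no count by as much. With the estimated correlation, limma's camera gave 1, 2, 1 and 2 lists at an unadjusted p under 0.05 for enzalutamide in control cells, the guides in vehicle, the guides in enzalutamide and the interactions, in that order. With own libraries limma gave 3588 genes for guide 1 in vehicle and 1241 for both guides at that level.

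With median-of-ratios scaling joined to an estimated inter-gene correlation the numbers of lists called were 8 for enzalutamide in control cells, 7 for the mean of the guides in vehicle, 2 for the mean of the guides in enzalutamide and 8 for the mean of the interactions. With array weights by the gene-by-gene method the counts of genes were 10264 for enzalutamide in control cells, 12392 for guide 1 in vehicle, 7916 for guide 1 in enzalutamide, 7045 for guide 2 in enzalutamide, 11394 for enzalutamide with guide 1, 11153 for the interaction with guide 1, 10844 for the interaction with guide 2, 8504 for guide 2 against guide 1 in enzalutamide, 3511 for both guides in vehicle, 2454 for both guides in enzalutamide and 3466 for both interactions, and OGDHL had -0.13 for interaction with guide 1 (call gained, adjusted p = 0.016). With the 2 guide 1 vehicle libraries of high mitochondrial share left out, where the 1 left is assumed to vary like the other groups, the counts of genes were 5274 for enzalutamide in control cells, 3 for guide 1 in vehicle, 2686 for guide 1 in enzalutamide, 814 for guide 2 in enzalutamide, 1934 for enzalutamide with guide 1, 3935 for guide 2 against guide 1 in enzalutamide, 3 for both guides in vehicle and 193 for both guides in enzalutamide, and OGDHL had -0.42 for guide 1 in vehicle (call lost, adjusted p = 0.60) and -0.69 for interaction with guide 1 (call gained, adjusted p = 0.0034). The sign turned for guide 1 in vehicle for PPP1R12C (0.060), HSD17B11 (0.013), PC (0.00016), MT-ND3 (-0.0022), PGK1 (0.036), GPI (0.00087) and ACLY (0.039). It also turned for the list of mitochondrially encoded genes in the mean of the interactions (0.25). With the 3 guide 2 vehicle libraries left out the counts of genes were 97 for guide 2 in enzalutamide, 593 for the interaction with guide 1 and 41 for both guides in enzalutamide. With median-of-ratios scaling and the same single guide 1 vehicle library the counts of genes were 8802 for enzalutamide in control cells, 35 for guide 1 in vehicle, 7157 for guide 1 in enzalutamide, 4615 for guide 2 in enzalutamide, 6100 for enzalutamide with guide 1, 4809 for the interaction with guide 1, 10258 for the interaction with guide 2, 8372 for guide 2 against guide 1 in enzalutamide, 13 for both guides in vehicle, 1298 for both guides in enzalutamide and 3246 for both interactions, and OGDHL had -0.67 for interaction with guide 1 (call gained, adjusted p = 1.1e-05). The sign turned for guide 1 in vehicle for SLC45A3 (0.022), HES6 (0.00031), PPP1R12C (0.083), HSD17B11 (0.031), SRD5A3 (0.012), TAP2 (0.0079), PC (0.021), PGK1 (0.067), GPI (0.035), KDM2B (0.0018), PCK2 (0.012), FDPS (0.00012), ACLY (0.072) and FADS2 (0.0018).

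Leaving out each library in turn (18 fits) gave these lowest and highest values: 2009 to 4990 for enzalutamide in control cells, 8 to 11235 for guide 1 in vehicle, 6157 to 9539 for guide 2 in vehicle, 557 to 2366 for guide 1 in enzalutamide, 68 to 678 for guide 2 in enzalutamide, 1491 to 9927 for enzalutamide with guide 1, 6109 to 9597 for enzalutamide with guide 2, 404 to 8771 for the interaction with guide 1, 4137 to 7930 for the interaction with guide 2, 8307 to 11482 for guide 2 against guide 1 in vehicle, 1020 to 3671 for guide 2 against guide 1 in enzalutamide, 3 to 2838 for both guides in vehicle, 25 to 163 for both guides in enzalutamide, 187 to 1725 for both interactions, -0.98 to -0.66 for OGDHL with guide 1 in vehicle, 0.29 to 0.42 for OGDHL with guide 2 in vehicle, -1.15 to -1.04 for OGDHL with guide 1 in enzalutamide, -0.71 to -0.61 for OGDHL with guide 2 in enzalutamide, 0.40 to 0.51 for OGDHL with enzalutamide in control cells, -0.45 to -0.13 for OGDHL in the interaction with guide 1, -1.10 to -0.96 for OGDHL in the interaction with guide 2, 15 to 16 for lists called for enzalutamide in control cells, 13 to 15 for lists called in the mean of the guides in vehicle, 3 to 5 for lists called in the mean of the guides in enzalutamide and 14 to 15 for lists called in the mean of the interactions. Of 7014 values of named genes 772 lost the call and 0 turned sign, and of 1992 list values 9 lost the call.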

Other observations

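Genes activated by the embryonic transcription factor DUX4, listed only after the first of them were seen, were higher in the libraries labelled guide 2 in vehicle. ZSCAN4, a gene of the early embryo, had 0.0420 ± 0.00983 TPM in control cells and 23.0 ± 2.96 TPM in those libraries (n = 3 each). PRAMEF12 had 0.314 ± 0.108 and 102 ± 13.3 TPM, H3Y1 0.563 ± 0.123 and 155 ± 26.8 TPM and LEUTX 0.0157 ± 0.00707 and 2.89 ± 0.535 TPM. Of 20 genes of the list 16 reached the filter on low values, 1 of them without these libraries, so calls among the filtered genes follow in part from the filter. With no filter limma called 20 of 20 higher, and 0 with guide 2 in enzalutamide, where 1 had an unadjusted p under 0.05. PRAMEF, TRIM and H3Y1 genes have near-identical copies, so their single values are uncertain, and no cause was tested.

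AIDA and its neighbour BROX were higher in enzalutamide in control cells, and a gain of the surrounding segment was a candidate explanation. The 54 other tested genes within 5 Mb of AIDA (chromosome 1, 222668013 to 222713210) had a median change at percentile 40.2 of such windows, which argues against a gain of the whole segment. Loss of the segment around OGDHL could lower its level with guide 1 in enzalutamide, but the 31 neighbours within 5 Mb had a median at percentile 69.7, which argues against loss of the whole segment. A gain or loss of single genes was not tested.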
